A study of Mus musculus with 2 samples.

How the data were processed

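Spleen immune cells of C57BL/6 mice were profiled by droplet single-cell RNA sequencing (10x Genomics Chromium, 3′ tags) in 1 WT library and 1 library from an RPA1 conditional knockout (CKO) mouse. The deposited values are whole UMI counts per gene and barcode, with no normalization, per the file headers. The submitters' processing notes name the mm10 genome, Cell Ranger 5.0.0 and Seurat 4.0.3, while the headers of the count matrices name Cell Ranger 6.0.2. Barcodes were already reduced to called cells before deposit, since the lowest barcode held 500 UMIs in the WT and 501 UMIs in the CKO library. Cell type annotations were not used here, so every class name was rebuilt from the counts, and a difference from the study can come from that alone.

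Cells with 200 to 6000 detected genes and under 10% mitochondrial UMIs were retained, which left 12679 of 13291 WT barcodes and 12610 of 12958 CKO barcodes. Doublets were scored in each library with Scrublet (scanpy 1.11.5) at an expected rate of 0.8% per 1000 cells. Its automatic threshold marked 532 WT cells (4.20%) but only 9 CKO cells (0.0714%), so the libraries would have been treated unlike. The rule used instead, set after that outcome was seen, marked scores at or above the quantile set by the expected rate (10.1% in both libraries). With tied scores this removed 1394 WT cells (11.0%) and 1293 CKO cells (10.3%). The remaining 11285 WT and 11317 CKO cells, with a median of 5334 and 4499 UMIs, entered the comparisons.

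Both libraries were clustered together without batch integration, on 2000 variable genes, 30 principal components and a shared-neighbour graph of 15 neighbours, with Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1, seed 0). T cell receptor and immunoglobulin segments, sex-linked genes and Rpa1 were kept out of the variable genes. Clusters were named from marker lists, with at least 3 markers detected in 10% of cells, and clusters whose 10 leading genes went against a name stayed unnamed. T-like clusters were clustered again to name CD4 T-like, CD8 T-like, Treg-like, γδ T-like and NKT-like cells. Cells of cycling clusters were placed into classes by their own markers, and among these a cell with 5 or more UMIs of erythroid marker genes, haemoglobin not among them, was left unnamed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

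With 1 library per genotype no test between genotypes was made. No p-value or standard error is given, and cells were not treated as replicates. Shares of cells carry exact Clopper-Pearson 95% intervals, CPM values (a gene's share of the UMIs summed over a class times 10⁶) carry exact Poisson 95% intervals, and CKO over WT ratios carry exact conditional binomial 95% intervals. These intervals, and the floors below, cover counting error only. A count of 0 was replaced by a floor of 3 counts over the summed class, which makes the ratio a bound. That bound leaves out the counting error of the other library, so the exact interval can reach nearer to 1. To compare shares of cells with a UMI across depths, each cell was thinned to 1000 UMIs and shallower cells were left out. Cycling cells were those with UMIs in at least 3 genes of the cycling list after thinning.

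For each of 28 gene lists the median log2 ratio of CPM (pseudocount 1 CPM) was taken over members with at least 20 summed counts, in the 8 classes with at least 100 cells in both libraries or named for a main comparison. Its counting interval comes from 1000 Poisson redraws, and its percentile from 10000 random lists of the same size, each member drawn from the 100 genes nearest in expression. The percentile describes these libraries and is not a p-value of the genotype. Members were counted at a fixed size of 1.5-fold. The lists cover the RPA and ATR checkpoint, DNA replication, DNA repair, p53 targets, apoptosis, cycling, type I interferon response, interferon gamma response, cytosolic DNA sensing, naive T cell, effector or memory T cell, cytotoxicity, T cell exhaustion, regulatory T cell, T follicular helper, T helper cytokines, immediate early and T cell receptor response, proximal T cell receptor signalling, cytokine receptors and survival, heat shock and dissociation stress, glycolysis, mitochondrially encoded genes, MHC class II presentation, B cell activation, haemoglobin, neutrophil granule and calprotectin, a sex-linked check and ribosomal proteins. Lists share some members, such as Ccl5 in both the effector and cytotoxicity lists. H2ax, Mx1, Mb21d1 and Sting1 had no entry under those symbols.

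Named genes followed a rule of size. A gene needed at least 20 CPM and 20 summed counts in a library, and at least 2% of its level in the class where it was highest in that library, as a guard against free RNA. Receptor and immunoglobulin segments, mitochondrial, ribosomal, sex-linked and unnamed genes were left out. Genes were ranked by the bound of the ratio interval nearest to 1, and the top 12 each way were taken in CD4 and CD8 T-like cells, 6 each way in Treg-like and B-like cells, and 3 each way in every other class with at least 100 cells per library. Rpa1, Rpa2, Rpa3 and 2 to 4 examples per list, those with the largest ratio in the direction described, were also named. The values of 2 genes that met the rule are not reported here. The class markers, gene lists, naming rule, intervals and the alternatives given below as fixed at the start were fixed before the data were examined. Positions are from the mm10 annotation.

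The steps were tested on simulated Poisson counts with the classes' real totals, with 200 genes altered 2-fold or 4-fold. In CD4 T-like cells (10662 genes) intervals covered the true ratio for 96.1% of genes, and 82.0% of 2-fold and 99.0% of 4-fold genes had an interval clear of 1. The matching recoveries were 71.1% and 79.6% in CD8 T-like cells (9905 genes), 53.7% and 83.5% in Treg-like cells (7313 genes), and 86.7% and 100% in B-like cells (12798 genes), with 0 genes called in the wrong direction. Unchanged random lists fell outside the 2.5 to 97.5 percentile range in 10 of 200 draws for CD4 T-like, 13 for CD8 T-like, 11 for Treg-like and 13 for B-like cells. The simulated counts were independent and followed the model of the intervals, so this checks the computation only. Real counts can gather in single cells and genes can vary together, so real intervals and percentile ranges can be too narrow.

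The alternatives fixed at the start were no cell filter, a stricter filter (500 genes, mitochondrial share under 5%), doublets retained, Leiden resolutions 0.6 and 1.6, classes from each cell's own marker UMIs, TMM scaling (edgeR 4.0.16, R 4.3.3), a total without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, the mean over cells of counts per 10000, a pseudocount of 5 CPM, no minimum count, no thinning or thinning to 2000 UMIs, and at least 2 cycling genes. Alternatives added after the data were seen were Scrublet's automatic thresholds, leaving out T sub-clusters with over 20 times as many cells of 1 library as of the other, leaving out T-like cells with a Trdc UMI, and cells per B-like cell. Exon-level, variant and receptor sequence analyses need reads and were not made here.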

Results

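Spleen immune cells of C57BL/6 mice were profiled by 3′ single-cell RNA sequencing in 2 libraries, 1 from a WT mouse and 1 from a mouse with a conditional knockout of RPA1 (CKO). RPA1 is the large subunit of replication protein A, which binds single-stranded DNA during replication, repair and checkpoint signalling. The WT library held 13291 barcodes, 84240951 UMIs and a median of 5355 UMIs and 1907 genes per barcode. The CKO library held 12958 barcodes, 76910129 UMIs and a median of 4616 UMIs and 1792 genes per barcode. The median mitochondrial share was 3.23% in the WT and 3.56% in the CKO library. The comparisons ask how the spleen's cell classes, and T cells above all, differed between these genotypes. With 1 library per genotype there was no replicate check and no test, and all values describe these libraries. The labels give neither the deleted exons nor the Cre driver. Class names were rebuilt from marker genes, so each is called a likeness.

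The targeted gene was examined first. Rpa1 (ENSMUSG00000000751, mm10 chromosome 11, 75298166 to 75348324, minus strand) was lower in CD4 T-like cells of the CKO library, at 34.1 CPM (27.6 to 41.5) against 47.6 CPM (43.9 to 51.5) in the WT library, a ratio of 0.716 (0.572 to 0.888). Over all T-like cells it measured 34.2 CPM against 43.4 CPM, a ratio of 0.787 (0.664 to 0.928). Treg-like cells gave 6 counts against 64, a ratio of 0.466 with an interval of 0.165 to 1.07. In CD8 T-like cells the ratio was 0.933 (0.607 to 1.38), from 27 against 365 counts. Outside T-like cells the Rpa1 ratio was 0.940 (0.871 to 1.01) in B-like, 0.964 (0.713 to 1.31) in marginal zone B-like and 0.967 (0.763 to 1.23) in NK-like cells. Fewer counts left it open in monocyte or macrophage-like cells, at 1.19 (0.736 to 1.98), and in conventional dendritic cell-like cells, at 1.32 (0.760 to 2.30). Of its partners in the trimer, Rpa2 gave a ratio of 0.883 (0.705 to 1.09) and Rpa3 one of 1.12 (0.953 to 1.30) over all T-like cells. A 3′ tag mostly reads the last exon, exon 17 of transcript Rpa1-202 (75298166 to 75301403), which holds the 3′ UTR (75298166 to 75301307), and a tag outside the deleted part checks nothing, so these counts do not show whether the gene was inactivated.

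**Figure D1:**
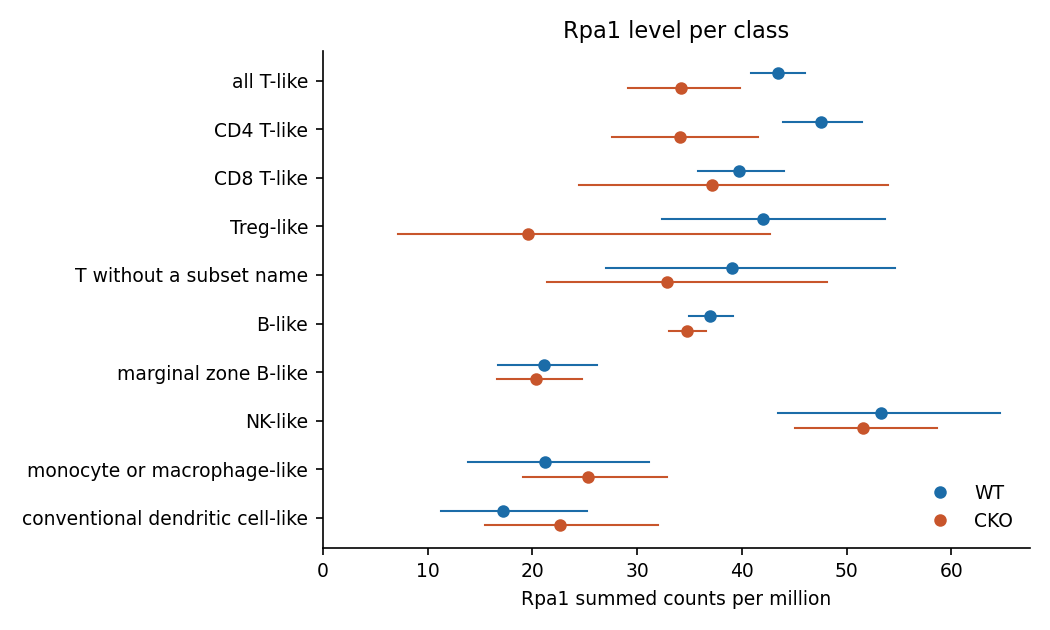
Rpa1 level per class, with CPM of the summed counts on the x axis, classes on the y axis, blue points for the WT and orange points for the CKO library, and lines for exact Poisson 95% intervals. CD4 T-like cells lie at 47.6 in the WT and 34.1 in the CKO library, while B-like cells lie at 37.0 and 34.8.

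The first comparison asks which cell classes the CKO spleen held in other proportions. T-like cells made up 31.6% (30.7 to 32.5) of WT cells and 6.67% (6.22 to 7.15) of CKO cells, 4.74-fold lower in the CKO library. CD8 T-like cells, the class of cytotoxic T cells, stood at 9.93% (9.39 to 10.5) and 0.822% (0.664 to 1.01), 12.1-fold lower. CD4 T-like cells, the helper class, were 4.12-fold lower at 4.24% (3.88 to 4.63) against 17.5% (16.8 to 18.2), and Treg-like cells, which carry Foxp3, were 3.60-fold lower at 0.566% (0.436 to 0.722) against 2.04% (1.79 to 2.32). NKT-like cells numbered 4 of 11317 in the CKO and 116 of 11285 in the WT library, a ratio of 0.0344 (0.00921 to 0.0904). They are all of T sub-cluster 10, which is itself found almost only in the WT library. γδ T-like cells, at 15 against 23 cells, gave a ratio of 0.650 (0.316 to 1.30), and T-like cells without a subset name gave 0.958 (0.720 to 1.28).

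Other classes took the larger shares that remained. B-like cells held 73.7% (72.9 to 74.5) of CKO and 55.6% (54.7 to 56.5) of WT cells, marginal zone B-like cells 5.31% and 3.96%, and monocyte or macrophage-like cells 2.03% and 1.20%. NK-like cells rested at 8.19% (7.69 to 8.71) against 3.54% (3.21 to 3.90). Among cells other than T-like ones the B-like ratio was 0.972 and the marginal zone B-like ratio 0.983, whereas NK-like cells stayed higher in the CKO library at 8.78% against 5.18%, a ratio of 1.69. Plasmacytoid dendritic cell-like cells, at 0.575 (0.364 to 0.904), and plasma cell-like cells, at 0.444 (0.228 to 0.839), were lower on that basis, but over all cells their intervals spanned 1, at 0.785 (0.496 to 1.23) and 0.605 (0.311 to 1.15). Conventional dendritic cell-like and neutrophil-like cells gave ratios of 1.07 (0.833 to 1.36) and 1.05 (0.755 to 1.46) over all cells, and 0.781 and 0.770 without T-like cells. Monocyte or macrophage-like cells gave 1.70 (1.37 to 2.12) over all cells and 1.25 without T-like cells. Unnamed cells made up 1.39% of the WT and 1.42% of the CKO library. Among them, cluster 20, with erythroid genes, held 0.567% and 0.433%, cluster 23 held 0.496% and 0.0707%, and cluster 30 held 0.0266% and 0.133%. Unnamed T sub-clusters 13, with B cell genes, and 15 held 0.142% and 0.133% of WT and 0.530% and 0.141% of CKO cells. Leaving out T sub-clusters found almost only in 1 library moved the Treg-like ratio from 0.277 to 0.490, against 0.172 at resolution 0.6 and 0.179 with the stricter filter, and left no NKT-like cells. With 1 library per group, a cluster mostly of 1 library may be that library, not a type.

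**Figure D2:**
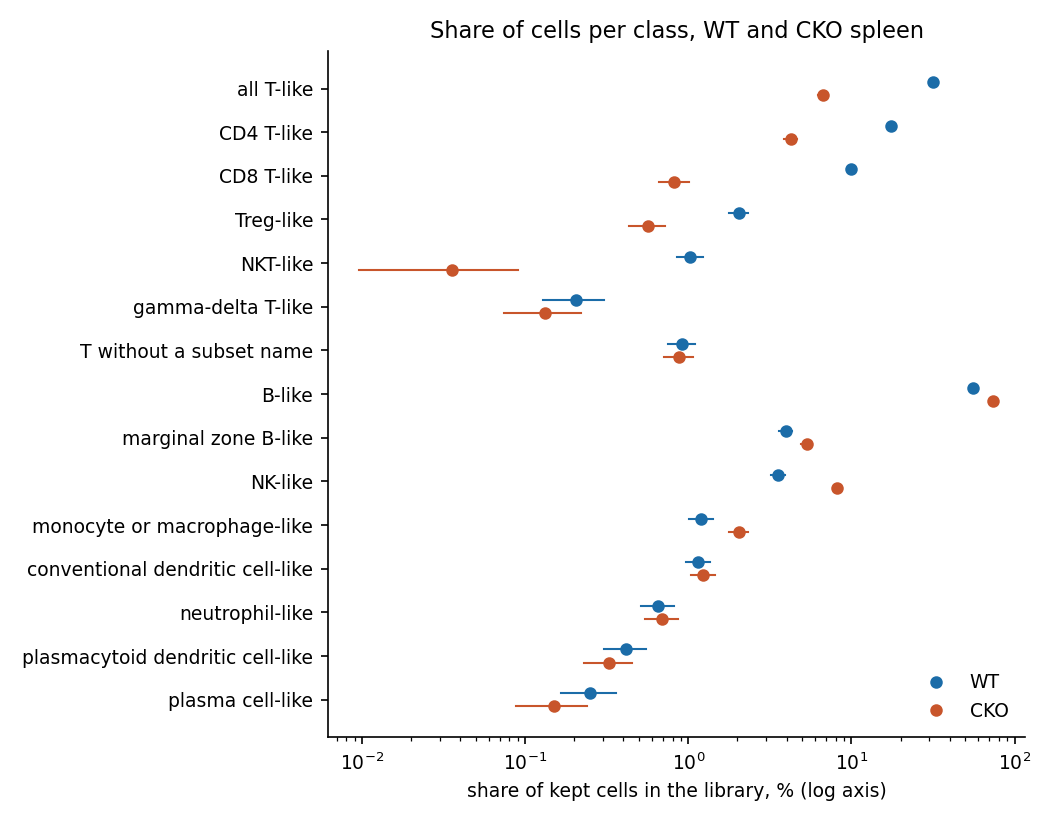
Share of cells per class in percent of each library's retained cells (x axis, log scale), with classes on the y axis, blue points for the WT and orange points for the CKO library, and lines for exact Clopper-Pearson 95% intervals. All T-like cells lie at 31.6% in the WT and 6.67% in the CKO library, and NK-like cells at 3.54% and 8.19%.

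The receptor genes of the T-like cells were examined after the shares were seen. T-like cells with no UMI of Trdc, the constant region of the δ receptor chain, were 5.90-fold lower in the CKO library, at 5.14% against 30.4% of cells. T-like cells with a Trdc UMI were not, at 1.53% (1.31 to 1.77) against 1.25% (1.05 to 1.47), a ratio of 1.22 (0.974 to 1.54). Those with a Trdc UMI and no UMI of Trac, the constant region of the α chain, numbered 103 in the CKO and 34 in the WT library, a ratio of 3.02 (2.03 to 4.59). Within CD8 T-like cells, 47.3% (36.9 to 57.9) of CKO cells and 3.39% (2.41 to 4.62) of WT cells held a Trdc UMI. After thinning to 1000 UMIs, which left out 0 cells, these shares were 32.3% and 0.714%. B-like cells, which should lack the gene, held one in 0.144% of CKO and 0.0956% of WT cells. Among NK-like cells 345 of 927 in the CKO and 122 of 400 in the WT library held one. A Trdc UMI alone therefore does not mark a γδ T cell. Median depth was 7603 and 7831 UMIs in CD8 T-like cells of the CKO and WT library, and 4195 and 4471 UMIs in B-like cells. CD8 T-like cells without a Trdc UMI were 22.2-fold lower in the CKO library, at 49 against 1083 cells, while those with one numbered 44 and 38. These were unlike in the libraries, since 77.3% of the CKO but 21.1% of the WT cells held a γ receptor UMI, and 45.5% and 89.5% held Trac. Trac was found in 71.0% of CKO and 94.5% of WT CD8 T-like cells.

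**Figure D3:**
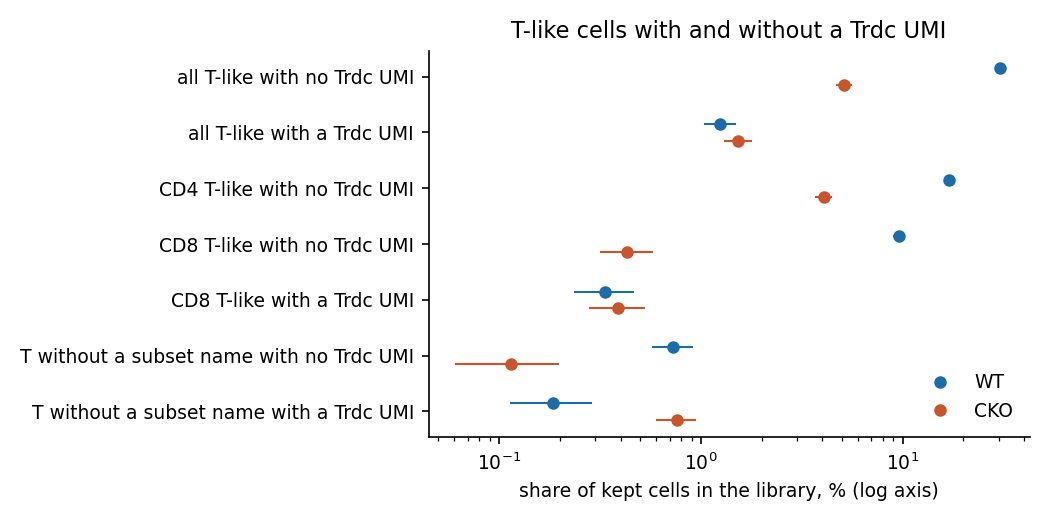
T-like cells with and without a UMI of Trdc, in percent of each library's retained cells (x axis, log scale), with the groups on the y axis, blue points for the WT and orange points for the CKO library, and lines for exact Clopper-Pearson 95% intervals. CD8 T-like cells without a Trdc UMI lie at 9.60% in the WT and 0.433% in the CKO library.

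CD4 T-like cells (1973 WT and 480 CKO cells) were compared to ask how the helper T cells that remained differed. Genes of effector and memory cells were lower in the CKO library, with 13 of 20 measured members of that list at least 1.5-fold lower and 0 higher, and a median log2 ratio of −0.79 (−0.98 to −0.65). That median was −0.17 with the stricter filter and −0.18 at resolution 0.6, and lower Cd8a, Nkg7 and Klrd1 leave CD8 T or other cytotoxic cells within the WT class not ruled out. Cxcr3, a chemokine receptor of T helper 1 cells, had a ratio of 0.168, Ly6c2 0.387 and S100a6, a calcium-binding protein, 0.341 (0.270 to 0.425), although S100a6 turned to 1.19 with the stricter filter. Maf, a transcription factor of follicular helper and interleukin-producing cells, was the gene most clearly lower, at 7.37 CPM against 35.9 CPM, 0.205 times (0.126 to 0.317). Among single genes, Sox4, a transcription factor active in thymocytes, was higher at 75.1 against 31.2 CPM (2.41 times, 2.03 to 2.84), and Ccr9, a gut and thymus homing receptor, at 23.9 against 10.4 CPM (2.30 times, 1.70 to 3.11).

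By rank, the genes most clearly higher in CD4 T-like cells were Drc1, an axonemal dynein regulator (6.34 times, 4.45 to 9.08), Tubb2a, a β-tubulin (3.15 times, 2.60 to 3.82), Myo6, an unconventional myosin (2.82 times), Sox4, Igf1r, the insulin-like growth factor receptor (2.36 times), Ift80, an intraflagellar transport protein, the cell cycle kinase Cdk6, Ccr9, Mxd1, the activation marker Nr4a1 (2.07 times, 1.64 to 2.59) and Rab6b. Those most clearly lower were Maf, F2rl1 (0.260 times), Cd8a (0.235 times), S100a6, Nkg7 and Klrd1 of cytotoxic cells (0.331 and 0.286 times), Dapl1 (149 against 345 CPM, 0.431 times), the histone gene Hist1h1b, Hopx, Ly6c2, Nacc2 and the integrin Itgb1 (0.430 times). Of the CKO counts of Hist1h1b, 56.1% came from 1 cell. All 24 kept an interval clear of 1 both without cells holding a Trdc UMI and without the sub-clusters found almost only in 1 library, but with the stricter filter Itgb1 turned to 1.005, as S100a6 turned. The genes were picked in these same cells, so the tally of 24 is no independent check. In B-like cells 3 of the lower genes, Dapl1, Cd8a and F2rl1, lay beyond 1.5-fold the same way, and 0 of the higher ones did. Those 3 stood at only 1.98, 1.40 and 0.974 CPM in WT B-like cells, where free RNA of T-like cells stays open.

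The lists fixed for T cell states had medians that were lower or near 0. The cytotoxicity list had a median of −0.74, or −0.61 with its member at 0 set to its bound, with 8 of 15 members lower, such as Tbx21, the master regulator of T helper 1 cells, at 0.169 times. Cd8a and Cd8b1 of CD8 T cells stood at 0.235 and 0.808 times in these cells, so the same limit holds for this list. T cell exhaustion had a median of −1.19 (−1.12 with members at their bound) and 9 of 12 members lower, among them Nt5e at 0.196 times, and Lag3 with 34 WT counts and 0 CKO counts. T follicular helper genes had a median of −0.68 with 6 of 10 lower, such as Cxcr5 at 0.295 times. T helper cytokines had a median of −0.35 with 4 of 9 lower, Ifng among them at 0.273 times (0.0723 to 0.732). The regulatory T cell list had a median of −0.07, with 2 of 13 higher and 5 lower, such as Nrp1 at 0.355 and Ctla4 at 0.364 times. Naive T cell genes had a median of 0.03, with Ccr9 higher and Il7r, the interleukin 7 receptor, lower at 0.536 times.

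By summed counts proliferation genes were lower and replication genes were not. The share of cycling cells showed no detectable difference, at 2 of 479 CKO and 12 of 1967 WT cells after thinning. The cycling list had a median of −0.69 (−0.98 to −0.56) with 15 of 24 members lower, led by Cenpf at 0.110 and Ube2c at 0.256 times, although a median of 56.2% of a member's CKO counts came from 1 cell. That median was −1.61 with no cell filter, −1.40 with the stricter filter, −1.51 at resolution 1.6 and −0.47 with a pseudocount of 5 CPM. DNA replication had a median of 0.17 with 2 of 27 higher, Mcm7 and Mcm2 (1.55 times) of the replicative helicase, and 2 lower. The RPA and ATR checkpoint list had a median of −0.07, with Chek1 at 2.29 and Timeless at 1.79 times as the 2 of 16 members that were higher. DNA repair (0.11, Blm at 1.71 times), p53 targets (0.10), apoptosis (0.04, with Bcl2l1 at 1.63 times and Bcl2a1b at 0.415 times), cytosolic DNA sensing (0.07), glycolysis (−0.01), proximal T cell receptor signalling (−0.02), immediate early genes (−0.03), mitochondrially encoded genes (−0.03) and ribosomal proteins (−0.01) stayed close to 0. The interferon gamma response had a median of −0.23, with 3 of 22 lower, such as Gbp2 at 0.584 times, and 1 higher. The type I interferon response lay at −0.11, with 2 of 37 lower, and turned to 0.01 when classes came from each cell's own markers. Heat shock genes had a median of 0.20, with 1 of 14 higher, Hspa1a at 3.56 times, and 1 lower. Cytokine receptors and survival genes had a median of 0.17, with 3 of 21 higher, such as Socs3 at 1.58 times, and 3 lower, such as Il2rb at 0.469 times. With no cell filter the DNA replication median turned to −0.04.

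Lists fixed mainly for other cell types or as checks were measured in CD4 T-like cells too. MHC class II genes had a median of −0.45, with H2-Aa at 0.474 times, which turned to 0.02 when classes came from each cell's own markers, and B cell activation genes one of −0.26, while neutrophil granule genes had a median of 0.67 (S100a8 at 1.94 times). The sex-linked list had a median of −0.13, with Eif2s3y, on the Y chromosome, at 0.312 times, and haemoglobin had too few measured members. As a description of these libraries, the effector, cytotoxicity, exhaustion, follicular helper, cycling and both interferon medians lay at percentile 0 of random matched lists, T helper cytokines at 0.095, and heat shock at 99.8. Sub-clusters 0, 2 and 3 held most CD4 T-like cells in both libraries, sub-cluster 5 was led by interferon genes such as Ifit3 and Isg15, sub-cluster 14 by immediate early genes such as Egr3 and Nr4a1, and sub-cluster 9, led in part by Itgb1, held 152 WT and 4 CKO cells. Without the sub-clusters found almost only in 1 library the effector median was −0.53, exhaustion −0.52, T follicular helper −0.31 and T helper cytokines −0.13, and the regulatory list turned to 0.26. At resolution 0.6 the cytotoxicity median turned to 0.06.

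CD8 T-like cells (1121 WT and 93 CKO cells) were compared to ask the same of the cytotoxic class. Genes of effector cells and killer receptors were higher in the CKO library. S100a6 stood at 368 CPM against 34.3 CPM (10.7 times, 9.09 to 12.7), the chemokine Ccl5 at 1707 against 462 CPM (3.69 times, 3.46 to 3.94), the activating receptor Klrk1 at 5.77 times (4.01 to 8.19), Klrc2 at 6.01 times and Cd163l1, a gene of γδ T cells, at 7.41 times (4.43 to 12.2). Lef1, a transcription factor of naive T cells, was lower (0.631 times, 0.559 to 0.709), as was Dapl1 (0.639 times). This class differs in makeup, since 47.3% of its CKO cells held a Trdc UMI.

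Among the higher genes of CD8 T-like cells, Cdkn1a, Cox6b2, Hist1h2ap, Hist1h2ab and Hist1h3c owed all their CKO counts to 1 cell each, and Top2a and Stmn1 owed 72.2% and 63.5% of theirs to 1 cell, so their ratios, such as 70.7 for Cdkn1a, describe single cells. The other genes most clearly lower were Rapgef4, Il6ra, a subunit of the interleukin 6 receptor (0.538 times), Vipr1, Lars2, Epsti1, Madd, Prelid2 (0.327 times), Rgs10 and Irf9, a transcription factor of the type I interferon response (0.519 times). Of the 12 higher genes 5, and of the 12 lower genes 2, lay beyond 1.5-fold the same way in B-like cells. Without cells holding a Trdc UMI, 11 of the higher and 10 of the lower genes kept an interval clear of 1. The genes were picked in these same cells, and a gene from 1 cell hinges on whether that cell was left out. The tally is therefore no independent check. S100a6 was then at 5.72, Ccl5 at 2.02 and Lef1 at 0.790 times.

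Effector or memory genes had a median of 0.67 (0.52 to 0.81) in CD8 T-like cells, with 11 of 20 higher, S100a4 at 4.73 times among them, and cytotoxicity genes one of 0.63, with 10 of 17 higher, such as Gzma at 4.94 times. Regulatory list genes had a median of 0.71 (Gpr83 at 6.76 times), cycling genes 0.68 (0.30 to 1.08; a median of 66.7% of a member's CKO counts came from 1 cell), cytokine receptors and survival genes 0.31 (Il2rb at 1.95 times), and DNA replication genes 0.41, with 8 of 26 higher and Gins2 at 3.29 times. Type I interferon genes had a median of −0.08 with 8 of 36 lower, interferon gamma genes −0.25 with Igtp at 0.576 times, and naive T cell genes −0.10. The p53 targets lay at 0.22, apoptosis at 0.23 (Bcl2 at 1.88 times, Bcl2a1b at 0.244 times), the RPA and ATR checkpoint at 0.07 (Chek1 at 5.16 times) and DNA repair at 0.22. The median of all genes in this class was 0.11, and TMM scaling moved all values by −0.18, so these medians are best read relative to it. Sub-clusters 1, 4 and 6 held most CD8 T-like cells in both libraries. Without cells holding a Trdc UMI, which left 49 CKO cells, the effector median was 0.32, cytotoxicity 0.13, the regulatory list 0.43 and cytokine receptors 0.15. Other medians lay further from 0, with DNA replication at 0.62, cycling at 0.88, p53 targets at 0.48, type I interferon at −0.34 and interferon gamma at −0.38, and DNA repair lay at 0.19. The cycling median turned to −0.16 with no cell filter, the replication median to −0.03 with the stricter filter, and the type I interferon median to 0.25 at resolution 0.6. At resolution 1.6 the interferon gamma median turned to 0.03.

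Treg-like cells (230 WT and 64 CKO cells) were compared to ask how the remaining regulatory cells differed. By the fixed lists, effector or memory T cell genes were lower in CKO Treg-like cells and naive T cell genes were higher. S100a6 had 1057 WT counts, from 81 cells, and 0 CKO counts, 70.8-fold lower with the floor taken over the group (ratio interval 0 to 0.0174). Klrg1, a receptor of terminally differentiated effector Treg cells, had 132 WT counts, from 32 cells, and 0 CKO counts, 8.85-fold lower at the floor (0 to 0.141). Maf was 20.5-fold lower (0.0488 times, 0.0132 to 0.126). Top2a and Hist1h1b, both of dividing cells, had 160 WT and 0 CKO counts each, 10.7-fold lower at the floor (0 to 0.116), although 29.4% and 45.0% of those counts came from 1 cell. The proliferation marker Mki67 had 201 WT counts (28.9% of them in 1 cell) and 1 CKO count, a ratio of 0.0247 (0.000623 to 0.139). Ccr9 was higher at 75.2 against 11.2 CPM (6.73 times, 3.44 to 13.4), as were Ly6c1 (3.52 times, 2.61 to 4.73), Stk26, Satb1, a chromatin organizer of young T cells, at 565 against 212 CPM (2.67 times, 2.21 to 3.22), Klf7 and Nsg2.

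In Treg-like cells all 21 measured members of the cycling list were lower, with a median of −4.46, or −2.29 with the 13 members at 0 set to their bound and a median of 32.1% of a member's WT counts from 1 cell. After thinning only 4 of 229 WT and 0 of 64 CKO cells met the cycling rule, a difference not detectable at this depth. Effector or memory genes had a median of −1.76 (−2.53 to −1.46) with 14 of 17 lower, led by Id2 at 0.0456 times. Naive T cell genes had a median of 0.59 (0.44 to 0.76) with 7 of 14 higher. The regulatory list had a median of −0.62 with 9 of 16 lower, Icos at 0.0836 times, while Foxp3, the factor that defines the lineage, stood at 1.16 and Ikzf4 at 1.64 times. T cell exhaustion had a median of −1.32 (−0.89 at the bound), T follicular helper −1.89, cytotoxicity −3.69 (−2.08 at the bound, 6 members measured), interferon gamma response −0.52, cytosolic DNA sensing −0.54 and glycolysis −0.36, with Tpi1 at 0.226 times. DNA replication (−0.08), DNA repair (−0.19), the RPA and ATR checkpoint (−0.09), p53 targets (0.09) and the type I interferon response (−0.10) lay near the median of all genes, −0.08. Sub-clusters 8 and 11 held most WT Treg-like cells (117 and 108), and sub-cluster 8 nearly all CKO cells (62, against 2 in sub-cluster 11), Klrg1 being among the leading genes of sub-cluster 11. Without it 5 of the 6 lower genes, picked in these same cells, kept an interval clear of 1. Klrg1, at 8 WT and 0 CKO counts, did not. The effector median was then −0.82, naive T cell 0.43, regulatory −0.28, and cytotoxicity turned to 0.48. DNA replication was then lower at −0.56, DNA repair at −0.52 and the RPA and ATR checkpoint at −0.53, while p53 targets lay at 0.03 and type I interferon at 0.09. Without cells holding a Trdc UMI the RPA and ATR checkpoint lay at −0.59, DNA replication at −0.04 and DNA repair at −0.18.

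B-like cells (6275 WT and 8342 CKO cells) were compared to ask which differences reached cells outside the T lineage. Aldh7a1, an aldehyde dehydrogenase on chromosome 18 (56509687 to 56572951), was higher at 122 against 12.1 CPM (10.1 times, 9.14 to 11.2). Genes of dividing cells were higher, with Mki67 at 66.7 against 35.7 CPM (1.87 times) and the histone genes Hist1h2ap (2.55 times, 2.38 to 2.74), Hist1h2ab (1.99 times), Hist1h1b and Hist1h3c, which turned to 0.735 times with the stricter filter and 0.560 times at resolution 1.6. Ifi208, an interferon-inducible gene, was lower at 2.48 against 21.5 CPM (0.115 times, 0.0931 to 0.142). Tsc22d3 (137 against 235 CPM, 0.583 times) and Ddit4 (0.588 times), both induced by glucocorticoids, were lower, as were the homing receptor Cxcr4 (0.573 times), the class I gene H2-Q7 (0.579 times) and Cdk5rap1 (0.507 times).

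The cycling list had a median of 0.53 (0.47 to 0.63) in B-like cells, with 10 of 24 higher, such as Ccna2 at 2.14 and Hmmr at 2.06 times. All 10 MHC class II genes lay within 1.5-fold, with a median of −0.30 (−0.31 to −0.28) and H2-DMb1 at 0.760 times. The interferon gamma response had a median of −0.23 (Nlrc5 at 0.531, Irf1 at 0.689 times), while the type I interferon response had one of 0.14, with 1 of 37 higher, Oas1a at 1.69 times, and 1 lower. Haemoglobin (1.09, Hbb-bs at 6.82 times) and neutrophil granule genes (0.73, Prtn3 at 5.38 times), which are genes of other cell types, were higher. The proximal T cell receptor signalling list was lower at −0.27, with the T cell marker Cd3g at 0.249 times, though not all its members are particular to T cells. The DNA replication (0.08), DNA repair (0.06), p53 (0.07), RPA and ATR checkpoint (0.03), apoptosis (0.03) and B cell activation (−0.07) medians were small. Marginal zone B-like cells shared the higher Aldh7a1 (5.69 times, 4.08 to 8.12) and Hist1h2ap and the lower Ifi208 (0.271 times), with Lpgat1 higher (1.79 times) and Lpcat2 and Pcp4 lower. Cluster 9 of the B-like cells was led by interferon genes such as Ifit3 and Oasl1, and cluster 7 by Egr3 and Nfkbid. The cycling median was 0.04 with the stricter filter and 0.00 at resolution 1.6.

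NK-like cells of the CKO library held more transcripts of dividing cells. All 24 cycling genes were higher, with a median of 2.88 (2.63 to 3.13), or 2.84 with 3 members at their bound, and Birc5 gave 213 counts against 1. That median was 1.13 with the stricter filter and 0.90 at resolution 1.6, and a median of 40.0% of a member's WT counts came from 1 cell. Genes of other cell types were higher in these cells too, with haemoglobin at 5.98 (5.66 at the bound), where a median of 96.8% of CKO counts came from 1 cell, and neutrophil granule genes at 0.87. Hist1h2ab had 421 CKO and 2 WT counts (91.6 times, 25.2 to 759), Hist1h3c 750 and 6 and Hist1h1b 1697 and 31. Nbea had 41 WT and 0 CKO counts, 31.4-fold lower at the floor (ratio interval 0 to 0.0410), and Ifi208 was lower at 0.158 times (0.0948 to 0.256), as was Cxcl10, whose counts came mostly from 1 cell. In monocyte or macrophage-like cells the heat shock genes Hspa1b (6.62 times, 4.32 to 10.6) and Hspa1a (3.99 times) were higher. They were not particular to this class. Hspa1b stood at 2.70 times in B-like, 4.34 in marginal zone B-like, 17.0 in NK-like and 1.20 in CD8 T-like cells. Hspa1a stood at 2.66, 6.70, 9.57 and 1.15 times in those classes. The B lineage genes Vpreb3 and Cd79a (2.05 times) were also higher in monocyte or macrophage-like cells. Mpo was lower at 0.0357 times (0.00943 to 0.0961), with UMIs in only 3 cells of each library, and Ms4a2 and Dqx1 came from 1 WT cell each. Conventional dendritic cell-like cells, whose cluster 13 was led in part by Hspa1a, had higher Ttn (8.82 times, 3.14 to 34.3), Ly6d (4.25 times) and Hspa1b (3.65 times). Ly6d was among the 10 leading genes of cluster 2 of the B-like cells. Cd79a was higher in these dendritic cell-like cells too, at 3.42 times (2.39 to 4.98), with 88.5% of its CKO and 95.1% of its WT counts from 10 cells. Transcripts of B-like cells, from the same droplet or as free RNA, were not tested here and stay open for Ly6d. Conventional dendritic cell-like cells had lower Ube2c, with 1 CKO and 52 WT counts (0.0206 times, 0.000511 to 0.120), Asprv1 and, from 1 WT cell, Fabp4. The WT counts of Ube2c came from 5 cells, 55.8% of them from 1 cell, and those of Asprv1 from 6 cells. The DNA replication median was 0.46 in monocyte or macrophage-like cells and −0.49 in conventional dendritic cell-like cells, where it reached 0.01 with doublets retained. Mpo turned to 1.05 times when classes came from each cell's own markers.

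The last comparison sets the classes beside each other, to ask which differences were shared by T, B and myeloid cells. The interferon gamma response had a negative median in all 8 classes, from −0.52 in Treg-like to −0.11 in NK-like cells, though few members passed 1.5-fold (1 of 20 in B-like, 0 of 18 in monocyte or macrophage-like cells) and the CD8 T-like median turned to 0.03 at resolution 1.6. The heat shock list had a positive one in all but Treg-like cells, where it was 0.00. Effector or memory genes went apart, at −0.79 in CD4 T-like, −1.76 in Treg-like, 0.67 in CD8 T-like and 0.10 in B-like cells. The contrast was smaller under some settings, at −0.17 in CD4 T-like cells with the stricter filter, −0.82 in Treg-like cells without sub-cluster 11 and 0.32 in CD8 T-like cells without Trdc UMIs. Cycling genes varied without a common line among T or other cells. They stood at −0.69 in CD4 T-like, −4.46 in Treg-like (−2.29 at the bound) and −1.15 in conventional dendritic cell-like cells, and at 0.68 in CD8 T-like, 0.53 in B-like and 2.88 in NK-like cells. At resolution 1.6 they were −1.51 in CD4 T-like, 0.00 in B-like and 0.90 in NK-like cells. With no cell filter they were −0.16 in CD8 T-like cells, and with doublets retained 0.02 in conventional dendritic cell-like cells. The difference between classes was not tested.

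Counted per cell after thinning, cycling cells made up 1.16% (0.945 to 1.42) of CKO and 0.671% (0.484 to 0.906) of WT B-like cells, a ratio of 1.74 (1.20 to 2.56), with 11 and 15 cells left out and unthinned shares of 2.33% and 1.72%. NK-like cells showed 18 of 923 against 1 of 390 cells, a ratio of 7.61 (1.20 to 317), or 2.54 for cells with at least 2 cycling genes, with 4 and 10 cells left out and unthinned shares of 3.88% and 1.25%. In CD4 T-like cells the shares were 0.418% (2 of 479) and 0.610% (12 of 1967), a difference not detectable at this depth, with 1 and 6 cells left out and unthinned shares of 1.67% and 1.57%. CD8 T-like cells had 2 of 93 against 8 of 1121 cells, with 0 left out and unthinned shares of 6.45% and 2.05%. Among CKO Treg-like cells 0 of 64 cells met the cycling rule, against 4 of 229 WT cells, with 0 and 1 left out and unthinned shares of 0% and 6.52%. The interval of the thinned ratio ran from 0 to 5.42, so that difference was not detectable at this depth. The exact interval allows up to 5.60% of CKO Treg-like cells meeting that rule. Thinning hides some cycling cells, so this does not cap the share of cycling cells.

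**Figure D4:**
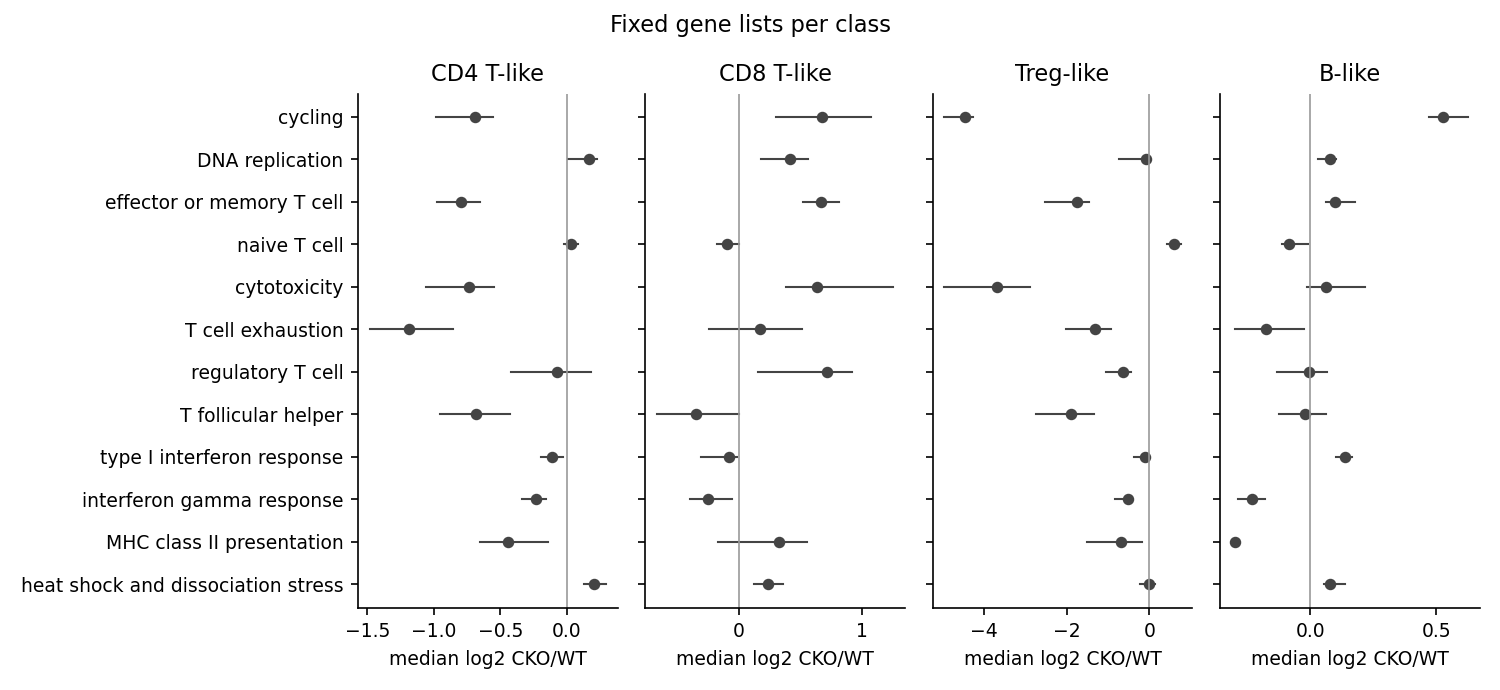
Median log2 CKO over WT ratio of 12 fixed gene lists (y axis) in CD4 T-like, CD8 T-like, Treg-like and B-like cells (panels), with lines for 95% intervals from Poisson redraws of the counts and each panel on its own x scale. The effector or memory list lies at −0.79 in CD4 T-like and 0.67 in CD8 T-like cells.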

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

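Results were recomputed under the alternatives that apply to them, and a value counted as the same if it lay within the counting interval of the main value. Cycling shares were recomputed only for thinning, the number of cycling genes and Trdc UMIs, and leaving out Trdc UMIs or sub-clusters was applied to T-like classes only. All 96 values of Rpa1 and all 14 of the cycling shares lay within their intervals, some of which are too wide to show stability. The cycling ratio ran from 2.54 to 7.61 in NK-like and from 0.587 to 1.06 in CD4 T-like cells, and the Rpa1 ratio from 0.436 to 0.711 in Treg-like cells. Of 94 values of class shares 75 stayed, 19 moved and 0 turned. Of 2706 list values 2419 stayed, 267 moved and 20 turned, and of 1045 values of named genes 902 stayed, 137 moved and 6 turned. Over all alternatives the T-like share ratio ran from 0.159 to 0.225 and the Rpa1 ratio in CD4 T-like cells from 0.682 to 0.736. The cause of the movements was not tested. No paired analysis was possible because each genotype had 1 library.

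With no cell filter the CD8 T-like share ratio was 0.108. The CD4 T-like medians were −1.61 for cycling and −0.044 for DNA replication, and the CD8 T-like medians −0.16 for cycling and 1.15 for effector or memory.

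The stricter filter gave share ratios of 0.194 for T-like and 0.179 for Treg-like cells. It turned S100a6 to 1.19 and Itgb1 to 1.005 in CD4 T-like cells and Hist1h3c to 0.735 in B-like cells. Its list medians were −1.40 (cycling) and −0.17 (effector or memory) in CD4 T-like, −0.028 (DNA replication) in CD8 T-like, 0.34 (naive) and −0.99 (effector or memory) in Treg-like, 0.045 (cycling) and −0.27 (MHC class II) in B-like, and −0.17 (DNA replication) in NK-like cells. The NK-like DNA replication median turned from a main counting interval of 0.095 to 0.35.

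With doublets retained the medians were 0.39 for cycling in B-like cells, and 0.012 for DNA replication, 0.024 for cycling and −0.015 for cytotoxicity in conventional dendritic cell-like cells. Scrublet's automatic thresholds gave 1.27 for the B-like share ratio, 0.38 for B-like cycling, −0.28 for B-like MHC class II, 0.21 for NK-like B cell activation, and 0.00056 for DNA replication and −0.0046 for cytotoxicity in conventional dendritic cell-like cells. The main counting intervals were −0.57 to −0.15 for NK-like B cell activation and 0.29 to 0.59 for conventional dendritic cell-like cytotoxicity, so both turned.

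Leiden resolution 0.6 gave share ratios of 0.188 for T-like, 0.269 for CD4 T-like and 0.172 for Treg-like cells. The WT library then held 382 Treg-like and 1721 CD4 T-like cells, against 230 and 1973 in the main setting. The CKO library held 66 and 464, against 64 and 480. Its list medians were −0.18 (effector or memory) and 0.057 (cytotoxicity) in CD4 T-like, 0.25 (type I interferon) in CD8 T-like, 0.35 (naive) and −1.04 (effector or memory) in Treg-like and 0.64 (cycling) in B-like cells. Resolution 1.6 gave a T-like share ratio of 0.194 and turned Hist1h2ap in CD8 T-like cells to 0.999 and Hist1h3c in B-like cells to 0.560. Its medians were −1.51 (cycling) in CD4 T-like, −0.014 (DNA replication), 0.20 (type I interferon) and 0.034 (interferon gamma) in CD8 T-like, 0.0025 (cycling) in B-like and −0.15 (DNA replication) in NK-like cells.

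Classes from each cell's own marker UMIs gave a monocyte or macrophage-like share ratio of 1.35 and Mpo at 1.05 in that class. The medians were 0.010 (type I interferon) and 0.017 (MHC class II) in CD4 T-like, 1.15 (effector or memory) and 1.63 (cytotoxicity) in CD8 T-like, −0.27 (MHC class II) in B-like and −0.13 (cytotoxicity) in monocyte or macrophage-like cells. The monocyte or macrophage-like cytotoxicity median turned from a main counting interval of 0.44 to 1.88.

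Without T-like cells holding a Trdc UMI the share ratio was 0.170 for T-like and 0.0452 for CD8 T-like cells, and the CD8 T-like medians were 0.32 (effector or memory) and 0.13 (cytotoxicity). Without the sub-clusters found almost only in 1 library the Treg-like share ratio was 0.490, and the medians were −0.53 (effector or memory) in CD4 T-like and 0.43 (naive), −0.82 (effector or memory) and 0.48 (cytotoxicity) in Treg-like cells. Per B-like cell the share ratios were 0.159 for T-like, 0.183 for CD4 T-like, 0.0624 for CD8 T-like, 1.01 for marginal zone B-like, 1.74 for NK-like and 1.28 for monocyte or macrophage-like cells.

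TMM scaling moved CD8 T-like effector or memory genes to 0.49 and B-like MHC class II genes to −0.33, and another total of counts moved the latter to −0.32. The mean over cells gave −0.53 for CD4 T-like cycling, −1.44 for Treg-like effector or memory and 0.38 for B-like cycling. A pseudocount of 5 CPM gave −0.47 for CD4 T-like and 0.37 for B-like cycling.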

Other observations

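Some B-like and cycling cells differed in number beyond the classes. Cluster 19 of the B-like cells, led by the recombinase gene Rag1 and by Vpreb3, both active in B cell precursors, held 0.831% of CKO and 0.177% of WT cells (4.69 times, 2.87 to 8.02). The cycling clusters held 211 of 8342 CKO and 111 of 6275 WT B-like cells, 19 of 927 and 2 of 400 NK-like cells, and 14 of 230 and 8 of 135 monocyte or macrophage-like cells. In T-like classes they held 2 of 480 against 14 of 1973 CD4 T-like, 4 of 93 against 15 of 1121 CD8 T-like and 0 of 64 against 5 of 230 Treg-like cells. Ifng, the cytokine of NK and T helper 1 cells, was higher over all CKO cells at 12.3 against 7.60 CPM (1.61 times, 1.44 to 1.80), while NK-like cells held it at 1.07 times (0.916 to 1.25). NK-like cells, whose share was higher in the CKO library, gave 568 of 789 CKO and 231 of 535 WT counts. Over all T-like cells, which differed in makeup, Ifng stood at 1.51 times (1.14 to 1.99), and in CD4 T-like cells at 0.273 times.

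Of the T-like cells without a subset name, those with a Trdc UMI numbered 86 in the CKO and 21 in the WT library, 4.08 times by share, and those without one 13 and 82, which is 6.33-fold lower. Most cells without a subset name lay in T sub-cluster 7 (92 CKO and 93 WT cells), whose leading genes include the NK markers Fcer1g, Tyrobp and Klrb1c. Trac UMIs were found in 0.563% of CKO and 2.20% of WT B-like cells. S100a8 UMIs, a neutrophil transcript, were found in 9.75% and 5.96% of them, although neutrophil-like cells had shares of 0.689% and 0.656%.

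All tests in the paragraphs below were chosen only after the result was seen. The lower share of T-like cells in the CKO library has 3 technical explanations. Cell filters or doublet calls could have removed T cells, but with either step left out the ratio was at most 0.216. More cells of other classes could have diluted all T-like cells alike, but T-like cells with a Trdc UMI had a ratio of 1.22, and those with Trdc and no Trac one of 3.02, where those without Trdc had 0.169. Without absolute cell numbers, shares cannot tell a loss of T-like cells without Trdc from a gain of all other cells. T cells could have been named as other classes, but 6 CD3 and receptor constant genes summed over all barcodes gave 583 against 2188 CPM, a ratio of 0.266. A loss of αβ T cells with the RPA1 knockout, and differences between the animals or their handling, stay open as untested.

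Trdc UMIs in CD8 T-like cells of the CKO library were found in 47.3% of cells. Free RNA could have carried them, but only 0.144% of B-like cells held one. NK-like cells in the same droplet could have, but only 2.90% of NK-like cells with Trdc held a γ receptor constant UMI, against 77.3% of these CD8 T-like cells. That share fits γδ T cells placed with CD8 T-like cells, as does Trac, held by 45.5% of them against 93.9% of those without Trdc. Since 20 of the 44 cells hold Trac, the nature of these stays open. Cells named γδ T-like held Trac too, in 26.7% (7.79 to 55.1) of 15 CKO and 52.2% (30.6 to 73.2) of 23 WT cells.

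Of 11106 genes, 24 had a ratio interval beyond 1.5-fold the same way in T-like and B-like cells, 10 higher and 14 lower in the CKO library, among them Aldh7a1 (8.45 times in T-like and 10.1 times in B-like cells), Prelid2 (0.228 and 0.246 times) and the Y-linked Eif2s3y (0.268 and 0.219 times). Loss of the Y chromosome or a mixture of sexes could lower Eif2s3y, but Ddx3y, also on the Y chromosome, stood at 1.02 times in B-like cells. Free RNA of B-like cells could carry Aldh7a1 into T-like cells, but its level there was 15.2% of the B-like level, against 0.728% for Cd79a. Free RNA of T-like cells stays open for Cd8a, Cd8b1, Dapl1 and F2rl1, which stood at 1.40, 2.28, 1.98 and 0.974 CPM in WT B-like cells against 192, 510, 381 and 30.9 CPM in T-like cells. For Hbb-bs and Jchain, marker genes of erythroid and plasma cells, free RNA was not tested and stays open too. The T-like class also differed in makeup, with CD8 T-like cells at 1121 of 3566 WT and 93 of 755 CKO T-like cells. S100a6, at 1.85 times over all T-like cells, stood at 0.341 times in CD4 T-like and 10.7 times in CD8 T-like cells. A ratio over all T-like cells can therefore reflect makeup, which was not tested for each gene. For the other genes a variant of the strain, or another difference between animals or libraries, cannot be told apart from the genotype with 1 mouse each.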
